A study of Homo sapiens with 4 samples.

How the data were processed

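Total RNA from PC9 and MTAC-P cells was measured on 4 one-colour arrays, 2 per line. Per the labels' protocols, cells were grown in DMEM with serum, RNA was extracted with Trizol, and a one-colour Agilent kit with the dye Cy3 was used for amplification and labelling. Per the submitters' processing notes, Agilent Feature Extraction 10.7 was used. The probe-set names of the deposited table and its control probe sets follow Affymetrix conventions. Most of the names were found in GEO's annotation of the platform, so the table itself is of Affymetrix type. How the Agilent kit and software named in the labels relate to it is not settled by the sources used here. The authors deposited log2 expression values, 1 value per probe set and array. The log2 scale was inferred from the values, which run from 3.32 to 14.6, and the background correction, normalization and summarization behind them are not recorded in the sources used here. Array medians over all probe sets were 4.87 and 4.85 for PC9 and 4.87 and 4.88 for MTAC-P, so the values were used without further scaling. The table holds no detection calls. Its background probe sets with 3 to 19 G or C bases averaged 3.82 in PC9 and 3.85 in MTAC-P. Those with 20 to 25 averaged 4.99 and 5.25. These probe sets were not used to set a detection level, so the level at which a gene is undetected was not determined.

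The table has 49386 probe sets. Of these, 93 are control probe sets, 45253 have 1 gene symbol in GEO's platform annotation, 1327 have several and 2713 are unnamed here. Symbols were updated by gene identifier to the reference gene table of assembly GRCh38.p14, in which 14944 of the 14970 tested genes were found. Each of 18239 genes was represented by its probe set with the highest mean over the 4 arrays. The 3269 genes whose mean lay under the 25th percentile of all probe sets' means, a log2 value of 4.14, were left out, and 14970 genes were tested. Control probe sets and probe sets with several symbols or no symbol were not used for gene results. Fold changes are given as MTAC-P over PC9 or the reverse, and they understate the difference of a gene whose level in the lower line is near background.

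The lines were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior variance, 2-sided), and p-values were adjusted over all tested genes by the Benjamini-Hochberg method at a threshold of 0.05. Standard errors (SE) are limma's moderated ones, intervals are 95% intervals and spreads are standard deviations (SD). With 2 arrays per line, the number of arrays limits the precision, and an exact permutation test cannot give a 2-sided p below 0.333. The labels call the arrays of a line duplicates without saying whether they come from separate cultures, so the spread between them may be technical. The 33 gene lists were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry. Within each list, p-values were also adjusted over the list alone. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

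The design, the lists, the rule for naming genes and most alternatives were set before the data were examined. The rule names, among genes past the threshold with a change of at least 2-fold, no overlap between the lines and a mean in the higher line at or above the median probe set, the 12 largest rises and 12 largest falls, leaving out provisional and family-type symbols (such as FAM), XIST and Y-linked genes. It also names up to 2 risen and 2 fallen members of each list, or, where none passed, the member with the largest difference, and always EGFR, ERBB2, ERBB3, MET, AXL, VIM, CDH1, FGFR1, IGF1R, BCL2L11, ABCB1 and MKI67. FAM171A1, list members named because they passed over their list alone or to fill out a group, and genes outside the lists were chosen after their values were seen.

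The alternatives were the replicate number as a block, centring on the median or the 75th percentile, quantile normalization, no dim filter or one at the 50th percentile, the mean of all probe sets of a gene, a variance trend, a robust prior, an unmoderated test, a pseudocount of 16 on the linear scale, leaving out each array, thresholds of 0.01 and a tested fold of 1.5, fold floors of 1.5 and 4, and camera on ranks. A threshold of 0.10 and the removal of a trend with gene length, gene density (genes within 500 kb on each side) and level by loess with a span of 0.5 were added after seeing the data. The limma and camera steps were tested on 20 simulated data sets of the comparison of MTAC-P with PC9 over 14970 genes, with 200 genes changed in each. The step recovered 26.3% of genes changed by 1 on the log2 scale, 93.8% of those changed by 2 and 98.7% of those changed by 3, with 7.45 wrong calls per simulation. A list of 25 genes shifted by 0.5 had an unadjusted camera p under 0.05 in 20 of 20 simulations, and an unshifted list in 1 of 20. The simulated genes varied independently, with a spread drawn from limma's fitted prior. Real lists were judged by an adjusted p over 33 lists and had estimated correlations of up to 0.50. These rates therefore need not hold for the data, in which SERPINB3, at a log2 difference of -3.33, was not called.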

Results

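Gene expression was measured in PC9, a human lung adenocarcinoma line with an activating EGFR mutation, and in MTAC-P, a lung cancer line that the labels describe as resistant and as raised under mild treatment with a tyrosine kinase inhibitor (TKI). The labels give no inhibitor, dose or parent line for MTAC-P, and they do not say whether drug was present when the cells were collected. There were 4 arrays, 2 for each line, and values are log2 expression values of a table of 49386 probe sets. Across the 14970 tested genes, Pearson's r was 0.992 between the PC9 arrays and 0.990 between the MTAC-P arrays, with genes counted as points and not as independent replicates. Between the lines r ranged from 0.980 to 0.990, the highest value being that of the replicate 1 arrays. Genes at least 2-fold apart numbered 192 between the PC9 arrays, 191 between the MTAC-P arrays and from 225 to 826 between arrays of different lines. The poly-A spike-in controls were 0.69 higher on the log2 scale in MTAC-P, on both arrays.

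The comparison of the lines asks which genes separate the resistant MTAC-P cells from PC9. LCP1, which encodes the actin-bundling protein L-plastin, fell from 10.66 ± 0.22 in PC9 to 7.25 ± 0.14 in MTAC-P (log2, SD, n = 2 per line), a 10.6-fold difference. BMP5, a ligand of the bone morphogenetic protein family, rose from 4.04 ± 0.17 to 6.47 ± 0.21, and its PC9 level lay below the value used to leave out dim genes. FAM171A1, which falls outside the naming rule and was chosen after its values were seen, rose from 4.84 ± 0.04 to 7.46 ± 0.30, a 6.15-fold difference. Among genes that did not pass the test, MTAC-P had higher means of VIM, AXL, WNT5A and XBP1 and lower means of PTGS2, CEACAM6, CLDN1 and S100A4.

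LCP1, BMP5 and FAM171A1 were the 3 genes past limma's adjusted p threshold. The log2 difference of LCP1 was -3.41 (SE 0.18, limma adjusted p = 0.0121), that of FAM171A1 was 2.62 (SE 0.19, limma adjusted p = 0.0373), and that of BMP5 was 2.43 (SE 0.19, limma adjusted p = 0.0373). The other probe set of LCP1 was also lower in MTAC-P, by a log2 difference of -2.07, whereas the other probe set of BMP5 was dim and differed by 0.084. The 3 probe sets of FAM171A1 differed by 0.47 to 2.62. With the mean of all probe sets, BMP5 differed by 1.26 and FAM171A1 by 1.34. A wider set of 2823 genes had an unadjusted p under 0.05, where 748 are expected with no difference, and 1161 of them were higher and 1662 lower in MTAC-P. Means were at least 2-fold apart for 303 genes, 60 higher and 243 lower in MTAC-P. The arrays of the lines did not overlap for 53.2% of genes, against the 33.3% that chance gives on average with 2 against 2 arrays. Genes on the same 4 arrays are not independent, so the excess over this share or over the 748 genes is not a test. Split by replicate number instead, the same arrays gave 96 genes at least 2-fold apart, and the remaining split of 2 against 2 gave 10. No gene passed without MTAC-P replicate 1 or without MTAC-P replicate 2, 68 passed without PC9 replicate 1, and none passed in the unmoderated test or with the mean of all probe sets of a gene. BMP5 and FAM171A1 also missed the threshold with the 50th percentile filter and with the pseudocount. The sizes of the differences moved little when 1 array was left out. LCP1 stayed between -3.57 and -3.26, BMP5 between 2.28 and 2.58 and FAM171A1 between 2.41 and 2.83.

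**Figure D1:**
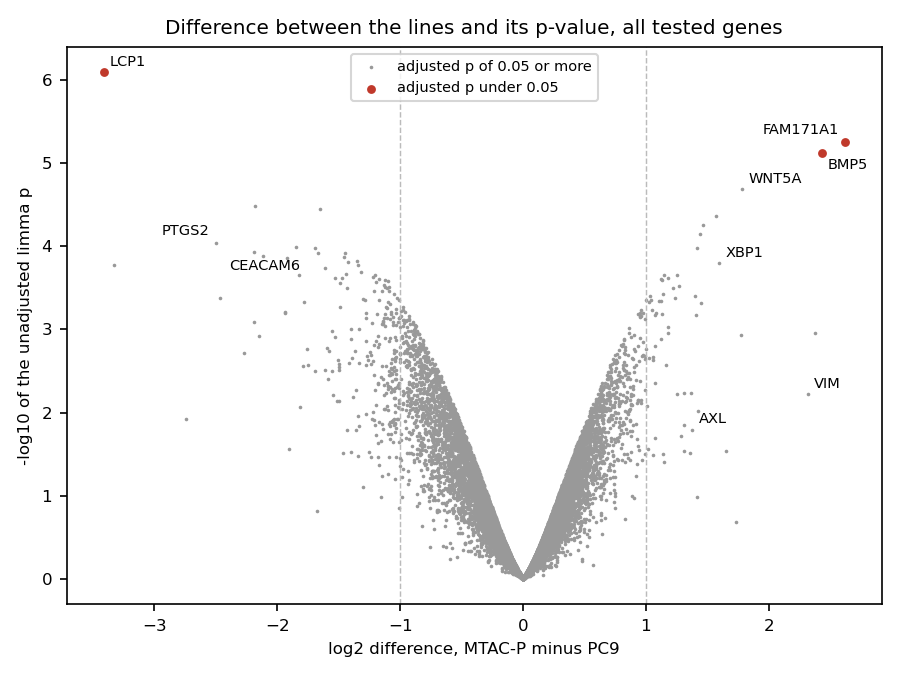
Each point is 1 of the 14970 tested genes, with the log2 difference MTAC-P minus PC9 on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis, and dashed lines at a 2-fold difference. LCP1, at -3.41, lies apart on the left, and FAM171A1 and BMP5, at 2.62 and 2.43, lie apart on the right.

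The gene lists asked whether pathways linked to TKI resistance or to cell identity differed between the lines. Of the 33 lists, 0 passed camera's adjusted p threshold and 8 had an unadjusted p under 0.05. With an estimated correlation 0 passed, with a lowest adjusted p of 0.831, and 0 had an unadjusted p under 0.05. In that version camera takes its degrees of freedom from the 4 arrays, so hardly any list could pass. Its high p is not in itself a sign of correlated genes. The estimated correlation was -0.00056 for the interferon and -0.032 for the Wnt list, below the preset 0.01. It was 0.088 for the unfolded protein list. With fry 0 passed and 4 had an unadjusted p under 0.05. No list member passed the limma test over all genes, so list members below are given as values, and 36 genes in 15 lists passed when adjusted over the list alone. Without PC9 replicate 1, 9 lists passed camera, against 1 without MTAC-P replicate 1 and 3 without MTAC-P replicate 2. The count adjusted over the list alone was 59 without MTAC-P replicate 1, of which 24 were shared, 69 with a variance trend and 3 in the unmoderated test. The medians of the bypass receptor, TGF-beta, YAP and TAZ, p53, BCL2, HLA, NF-kB, Notch, metallothionein, lung lineage, neuroendocrine, blood and heat shock lists changed sign when 1 array was left out. In 21 of the 33 lists the median differed more between the duplicates of at least 1 line than between the lines. Duplicate differences rest on single arrays and line differences on means of 2, so such a count would be high even with no line effect. Of 78 genes followed under the alternative settings, 23 had a difference that moved by more than 1.5 times or turned sign when 1 array was left out, and 16 had a probe set above the dim value with the opposite sign. With the mean of all probe sets of a gene, 41 of the 78 moved by more than 1.5 times or turned sign.

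EGFR, the receptor that TKIs of PC9 cells usually target, had nearly equal means in PC9 and MTAC-P, 10.65 ± 0.012 and 10.58 ± 0.31 (SD, n = 2). The log2 difference of EGFR was -0.078 (95% interval -0.55 to 0.39), its 8 probe sets ranged from -0.78 to 0.76, and its sign turned when the trend with gene length, density and level was removed. ERBB2 differed by -0.034 and ERBB3 by -0.074, and the sign of ERBB2 turned with quantile normalization. Of the 14 tested ERBB receptors and ligands, 3 were higher and 11 lower in MTAC-P, and 3 ligands passed when adjusted over the list alone. HBEGF was higher in MTAC-P by a log2 difference of 0.96 (SE 0.15) and NRG1 by 1.26 (SE 0.31), while BTC differed by -0.95 (SE 0.23). The 8 probe sets of NRG1 ranged from -0.26 to 1.26, and its difference was 0.82 without MTAC-P replicate 1.

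AXL, a receptor tyrosine kinase studied as a bypass of EGFR inhibition, was 2.60-fold higher in MTAC-P, with a log2 difference of 1.38 (SE 0.42) and non-overlapping arrays. The difference of AXL was 0.80 without PC9 replicate 2 and 1.95 without PC9 replicate 1. MET differed by -0.34, FGFR1 by -0.44 and IGF1R by -0.32, and the arrays of the lines overlapped for these 3 genes. With the mean of all probe sets, MET differed by -0.058, FGFR1 by -0.062 and IGF1R by -0.045. Of the probe sets above the dim value, 2 of 5 for MET, 2 of 5 for FGFR1 and 4 of 7 for IGF1R had the opposite sign. Leaving out 1 array moved MET between -0.64 and -0.050, FGFR1 between -0.75 and -0.13 and IGF1R between -0.65 and 0.0076. Of the 25 tested bypass receptor kinases and ligands, 13 were higher and 12 lower, with a median of 0.026, and 0 passed over the list alone. Of the 24 genes of ERK pathway output and feedback, 15 were higher in MTAC-P, the largest difference being 1.15 (SE 0.45) for the feedback inhibitor SPRY1, which was 0.40 without MTAC-P replicate 2. The efflux pump ABCB1 differed by 0.19 and the pro-apoptotic BCL2L11 by -0.13, and the sign of BCL2L11 turned with the mean of its 14 probe sets and with the trend removed. Of the 12 drug efflux transporters, 9 were lower in MTAC-P, with ABCC2 at -0.72 (SE 0.19) and ABCA3 at 0.80 (SE 0.18) passing over the list alone. The median of the efflux list was -0.24 between the lines and -0.32 between the PC9 duplicates. Among 15 BCL2 family genes 11 were higher, led by BID at 0.74, and among 25 p53 targets 16 were higher, although RRM2B had the largest difference at -1.34. Leaving out 1 array moved BID between 0.27 and 1.21 and RRM2B between -2.17 and -0.52, and the mean of the 9 probe sets of RRM2B differed by -0.21.

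Among mesenchymal genes, VIM, the intermediate filament vimentin, was 4.99-fold higher in MTAC-P, at 7.56 ± 1.25 against 5.24 ± 0.65 in PC9 (SD, n = 2). Its log2 difference of 2.32 was 1.44 without MTAC-P replicate 1 and 3.20 without MTAC-P replicate 2. CDH2 was higher by a log2 difference of 0.87, TWIST2 by 1.12 and COL5A1 by 0.84, while S100A4 differed by -1.67. VIM, CDH2, TWIST2, COL5A1 and S100A4 passed over the list alone, and 19 of the 29 tested mesenchymal genes were higher in MTAC-P. Many of the 29, among them ZEB1, COL1A1 and SPARC, had means close to the dim value of 4.14 in both lines, so this count says little. TAGLN, which did not pass, differed by -1.17 (SE 0.46). A second probe set of TWIST2 differed by -0.11 and one of COL5A1 by -0.29. Of the 35 epithelial genes, 15 were higher and 20 lower, with the tight junction gene CLDN1 at -1.47 (SE 0.20) and the surface protein gene CD24 at -1.20 (SE 0.17) passing over the list alone. E-cadherin, encoded by CDH1, differed by -0.54 (SE 0.16). The camera adjusted p was 0.440 for mesenchymal and 0.374 for epithelial genes. Of the 18 integrins and laminins 10 were lower, and LAMA4, ITGB6 and ITGB8 passed over the list alone at -1.69, -1.69 and -0.94. Another probe set of ITGB6 differed by -0.0068, one of LAMA4 by -0.038, and the list's median, -0.21, changed sign with the mean of all probe sets.

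**Figure D2:**
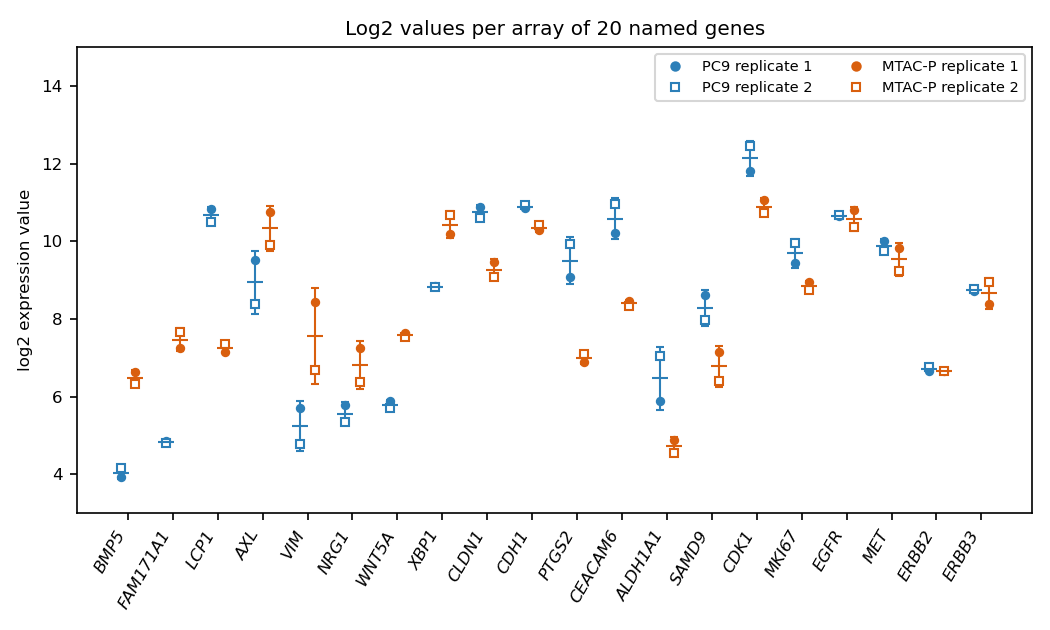
Each symbol is the log2 expression value of 1 gene on 1 of the 4 arrays, coloured by line, with circles for replicate 1 and squares for replicate 2, and bars give the mean and SD of each line. LCP1 lies near 10.66 in PC9 and 7.25 in MTAC-P, whereas the EGFR values of the lines overlap.

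The unfolded protein and amino acid stress list had the lowest camera p, with 23 of 29 genes higher in MTAC-P and a median log2 difference of 0.28 (camera adjusted p = 0.0827). With an estimated correlation, where 4 arrays leave camera little power, the adjusted p was 0.831. XBP1, a transcription factor of the unfolded protein response, was 3.03-fold higher (log2 difference 1.60, SE 0.20), and it lies in a run of neighbouring genes that were mostly higher in MTAC-P. PHGDH, the first enzyme of serine synthesis, differed by 1.14, asparagine synthetase ASNS by 1.01 (0.61 without PC9 replicate 2) and mitochondrial SHMT2 by 0.65. SDF2L1 and CHAC1 also passed over the list alone as higher, at 0.83 and 0.59, and DNAJC3 and SLC7A11 passed as lower, at -0.84 and -0.93. SLC7A11, which imports cystine, and GCLC, which acts in glutathione synthesis and differed by -0.92, passed within the NRF2 targets, of which 18 of 26 were lower (camera adjusted p = 0.185). The 3 probe sets of SLC7A11 ranged from -0.94 to 0.52. Of the 27 genes of cholesterol and lipid synthesis 18 were higher and of the 30 hypoxia and glycolysis genes 20 were higher, and 0 genes of either list passed over the list alone. HMGCS1 had the largest difference of the former, -0.70, and CA12 of the latter, -0.87, and without PC9 replicate 1 HMGCS1 differed by -0.014, while CA12 differed by -0.37 without PC9 replicate 2. Of the 8 tested metallothioneins 5 were higher, led by MT1G at 0.42 (0.096 without PC9 replicate 2).

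The Wnt list had 15 of 21 genes higher in MTAC-P and a median of 0.24 (camera adjusted p = 0.106). With an estimated correlation, where 4 arrays leave camera little power, the adjusted p was 0.831. WNT5A, a secreted ligand, was 3.44-fold higher (log2 difference 1.78, SE 0.16) on its brightest probe set. The 5 probe sets of WNT5A, 3 of them above the dim value, ranged from 0.075 to 1.78, and their mean differed by 0.60. SFRP1, a secreted Wnt antagonist, differed by 1.41 (SE 0.23) and the receptor gene FZD10 by 1.08 (SE 0.20), and all 3 passed over the list alone. The 4 probe sets of SFRP1 ranged from 0.32 to 1.41, and their mean differed by 0.90. The 3 probe sets of FZD10, whose mean was 4.80 in PC9, ranged from 0.14 to 1.08, and with their mean FZD10 differed by 0.59. Of the 21 Notch genes 13 were higher, led by the ligand gene DLL3 at 0.65 (SE 0.15). In the TGF-beta response list 11 genes were higher and 10 lower, and ID1, SKIL and TGFBR1 passed over the list alone at -1.33, -0.86 and -0.83. The other probe set of TGFBR1 above the dim value differed by 0.42. The median of this list was 0.049 and its mean -0.028. Camera, which compares limma's test statistics and not log2 differences, gave the direction as lower in MTAC-P.

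Interferon response genes were mostly lower in MTAC-P, 31 of 43, with a median of -0.17 (camera adjusted p = 0.0827). With an estimated correlation, where 4 arrays leave camera little power, the adjusted p was 0.831. SAMD9, an interferon-induced gene, had the largest difference, -1.50 (SE 0.31), and 0 genes of the list passed over the list alone. Of 15 genes of HLA class I and antigen processing 8 were lower, led by ERAP2 at -0.77, and of 11 HLA class II genes 6 were lower, led by HLA-DMA at -0.68. The HLA class II genes had means of 5.21 or less in both lines, close to the dim value of 4.14, so their count says little. PTGS2, which encodes the inducible cyclooxygenase, was 5.66-fold lower in MTAC-P (log2 difference -2.50, SE 0.29) and passed over the list of NF-kB targets and cytokines alone, in which 14 genes were higher and 13 lower.

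Of the 23 tested YAP and TAZ targets, 14 were higher in MTAC-P, and IGFBP3, at -1.42 (SE 0.18), passed over the list alone. CCN2, a connective tissue growth factor, had the largest difference of this list and of the TGF-beta list, 1.73 (SE 1.24), with overlapping arrays, since its PC9 arrays differed by 4.14. Replicate 1 lay above replicate 2 in both lines in the YAP and TAZ list, by a median of 0.62 in PC9 and 0.33 in MTAC-P, and below it in the NF-kB list, by medians of -0.28 and -0.44. The log2 difference between the 3' and 5' probe sets of ACTB was 1.71 and 2.49 on the PC9 arrays and 1.51 and 1.75 on the MTAC-P arrays, so replicate 2 had the higher value in both lines. For GAPDH the duplicates were close, at -0.057 and 0.038 on the PC9 arrays and -0.090 and -0.069 on the MTAC-P arrays.

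Of the 47 proliferation genes 27 were lower and 20 higher in MTAC-P, with a median of -0.047 (camera adjusted p = 0.185). Among the higher ones were CDT1 at 0.59 (SE 0.20) and MCM2 at 0.58 (SE 0.23). The mitotic kinase gene CDK1 differed by -1.24 (SE 0.25), with 3 probe sets from -1.24 to 0.34, and the proliferation marker MKI67 by -0.84 (SE 0.22), with 6 probe sets from -0.96 to -0.39. Of 13 replication-dependent histones 9 were higher, and the linker histone gene H1-2, at 0.98 (SE 0.16), passed over the list alone. In 16 stem cell and drug tolerance markers 11 were lower, with ALDH1A1, an aldehyde dehydrogenase, at -1.75 (SE 0.37) and CD24 passing over the list alone. Ribosomal proteins had a median of 0.0070, with RPL7 at -0.53, respiratory chain genes a median of 0.080, with COX6C at -0.49, and heat shock and immediate stress genes a median of 0.033, with EGR1 at 0.64 (SE 0.56). The signs of the ribosomal and heat shock medians turned under some settings.

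Lung lineage genes were higher in MTAC-P for 14 of 21, but apart from ABCA3 and ETV5 these 14 had means of 5.37 or less in both lines. Such levels are close to the dim value of 4.14, so the count says little. Among members at higher levels, FOXA1 differed by -0.41 (SE 0.31), LAMP3 by -0.39 (SE 0.33), MUC1 by -0.36 (SE 0.23) and LPCAT1 by -0.21 (SE 0.34). None of these genes passed over the list alone. With the 50th percentile filter the list's median was -0.10. CEACAM6, a cell adhesion gene, was lower in MTAC-P by 4.55-fold (log2 difference -2.18, SE 0.26). The 3 probe sets of CEACAM6 ranged from -2.18 to -0.44, and their mean differed by -1.04. CEACAM6 and ABCA3, a lipid transporter of alveolar cells, passed over the list alone. Squamous markers were lower for 9 of 12 genes, with a median of -0.22 between the lines and -0.34 between the PC9 duplicates. SPRR1A, at 4.98 and 8.55 on the PC9 arrays and 4.68 and 5.49 on the MTAC-P arrays, differed by -1.68 (SE 1.04), and by 0.11 without PC9 replicate 2. Of 10 neuroendocrine markers 5 were higher and 5 lower, and SCG2, at -0.79 (SE 0.15), passed over the list alone. Of 14 blood, endothelial and fibroblast markers 7 were higher and 7 lower, led by PDGFRB at -0.45 (-0.21 without PC9 replicate 2). Apart from UCHL1, ENO2 and CD68, the neuroendocrine and blood markers had means of 5.50 or less in both lines, so these counts say little. Of the 5 tested cancer testis antigens 4 were higher, led by CTAG2 at 0.40. The signs of the lung lineage, neuroendocrine, blood and cancer testis medians turned under some settings.

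**Figure D3:**
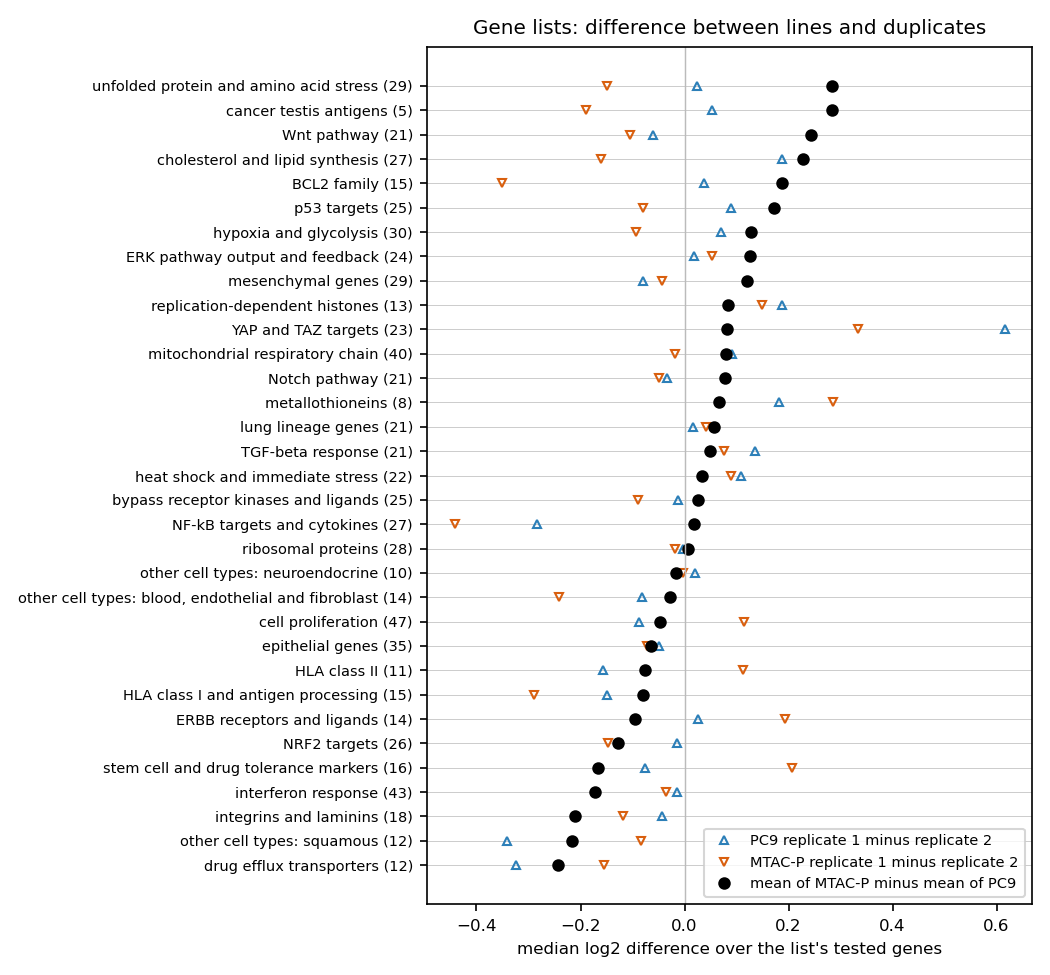
For each gene list, with its number of tested genes in brackets, the black circle is the median log2 difference MTAC-P minus PC9, and the triangles are the medians of replicate 1 minus replicate 2 within PC9 and within MTAC-P. The YAP and TAZ targets have the triangles farthest to the right, at 0.62 and 0.33, and the unfolded protein list has its black circle at 0.28.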

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

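All tests in this part were chosen after the results were seen. Some kinds of control probe sets, which enter no gene test, had both MTAC-P arrays above both PC9 arrays. MTAC-P minus PC9 on the log2 scale was 0.58 for the poly-A spike-in dap, 0.65 for lys, 0.71 for phe and 0.80 for thr. It was 0.27 for the hybridization control bioB, 0.20 for bioC, 0.031 for background probes with 3 to 19 G or C bases and 0.26 for those with 20 to 25. The hybridization controls bioD (0.083) and cre (0.023) and the Tag controls (-0.0072) did not separate the lines in this way.

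The poly-A spike-ins, which in Affymetrix-type designs enter the RNA before labelling, stood 0.69 higher in MTAC-P, while the hybridization controls, which enter after it, stood 0.16 higher. A brighter hybridization or scan would raise both kinds alike at a similar level, but dap minus the mean of bioB and bioC was still 0.34 higher in MTAC-P, with a largest difference between duplicates of 0.19, which argues against it as the whole account. More spike-in added per RNA and less mRNA per total RNA in MTAC-P cannot be told apart, since both predict higher spike-ins and the 28S ribosomal RNA probe set, at -0.031, separates neither. A lower mRNA content of MTAC-P cells stays a hypothesis, since no measurement of RNA amount is available to test it.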

How the results depend on the processing

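LCP1, BMP5 and FAM171A1 passed under median and 75th percentile centring, quantile normalization, no dim filter, a robust prior, without PC9 replicate 2 and with the length, density and level trend removed. That trend and the threshold of 0.10 were chosen after seeing the data. With the replicate number as a block, 2079 genes passed (687 higher, 1392 lower), 303 of them at least 2-fold apart, and 4 lists passed. Adjusted over their list alone, 137 genes passed, against 36 without the block. With 4 arrays the block leaves almost no residual information per gene, so these calls rest on the variance pooled over genes. The 303 are all the genes with means at least 2-fold apart, so the blocked fit acted much like a cutoff on the size of the difference. The labels do not say that the numbers pair the cultures, and the correlation of replicate 1 minus 2 between the lines, across genes, was 0.28. Genes passed, with and without the 2-fold floor, were 1 with the 50th percentile filter, 1 with the pseudocount, 0 with the mean of all probe sets (2667 at an unadjusted p under 0.05) and 0 in the unmoderated test (1655). A variance trend gave 77, of which 60 at least 2-fold apart. The threshold of 0.01 gave 0, a tested fold of 1.5 gave 1, and the threshold of 0.10 gave 124, of which 103 at least 2-fold apart. Leaving out arrays gave 0 to 68 genes, the 0 without either MTAC-P array and the 68 without PC9 replicate 1; the lone array is then assumed to vary like the pair. Lists passed were 3 with no dim filter, 2 with the mean of all probe sets, 1 with a variance trend, 1 with the trend removed, 2 at the threshold of 0.10, and 0 to 9 leaving out arrays. Differences turned sign for EGFR (0.15) and BCL2L11 (0.015) with the trend removed, ERBB2 (0.011) with quantile normalization and BCL2L11 (0.20) with the mean of probe sets. List medians turned sign with the mean of probe sets for TGF-beta response (-0.068), HLA class I and antigen processing (0.036), neuroendocrine (0.022), blood, endothelial and fibroblast (0.042) and integrins and laminins (0.068). With the trend removed they did for TGF-beta response (-0.030), metallothioneins (-0.014), ribosomal proteins (-0.0099) and heat shock (-0.0014). Neuroendocrine turned with 75th percentile centring (0.012) and no filter (0.061), cancer testis antigens with no filter (-0.026), ribosomal proteins with median centring (-0.0072), heat shock with the pseudocount (-0.0029), and lung lineage (-0.10) and blood (0.14) with the 50th percentile filter. Ranges that turn sign on leaving out arrays were -0.34 to 3.81 for CCN2, -3.46 to 0.11 for SPRR1A, -0.091 to 1.38 for EGR1, -0.30 to 0.14 for EGFR, -0.084 to 0.016 for ERBB2, -0.36 to 0.21 for ERBB3, -0.65 to 0.0076 for IGF1R and -0.056 to 0.43 for ABCB1. For list medians they were -0.031 to 0.052 for bypass receptors, -0.14 to -0.0029 for TGF-beta response, -0.37 to 0.28 for YAP and TAZ, -0.051 to 0.16 for p53, -0.15 to 0.44 for BCL2, -0.30 to 0.18 for HLA class I, -0.22 to 0.068 for HLA class II, -0.41 to 0.34 for NF-kB, -0.022 to 0.17 for Notch, -0.051 to 0.21 for metallothioneins, -0.0027 to 0.093 for lung lineage, -0.16 to 0.056 for neuroendocrine, -0.11 to 0.13 for blood, and -0.053 to 0.11 for heat shock. The cause was not tested. Background probe sets were not used to set a detection level, so the level under which a difference cannot be seen was not determined.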

Other observations

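All tests in this part were chosen after the results were seen. Outside the lists and besides LCP1, among genes that meet the naming rule on symbols and level, the largest differences toward a lower level in MTAC-P belonged to SERPINB3 (log2 difference -3.33, SE 0.42), SERPINA3 (-2.74, SE 0.79), RARRES1 (-2.47, SE 0.37), SERPINB4 (-2.27, SE 0.45) and SPRR3 (-2.19, SE 0.37). SERPINB3, SERPINB4 and SERPINA3 encode protease inhibitors of the serpin family, and SPRR3 a protein of the squamous cell envelope. Besides BMP5 and FAM171A1, the largest toward a higher level were those of the collagen gene COL13A1 (2.37, SE 0.42), DENND2A (1.78, SE 0.32), CYB5R2 (1.65, SE 0.59), NTNG2 (1.57, SE 0.16) and TMEM171 (1.45, SE 0.22). None of these 10 genes passed the limma test over all genes, the arrays of the lines did not overlap for any of them, and they were chosen after their values were seen. SERPINA3 differed by -1.36 without PC9 replicate 2 and CYB5R2 by 0.72 without MTAC-P replicate 2. With every probe set tested separately, 1 of 49386 passed and 636 had means at least 2-fold apart, 30 of them among the 2713 unnamed ones.

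Some gene lists differed alike between the duplicates of both lines. The sign was the same in both lines for 22 of 33 lists and opposite for 11, such as proliferation (-0.088 in PC9, 0.11 in MTAC-P) and cholesterol synthesis (0.19 and -0.16), and Spearman's rho across the lists was 0.32. The YAP and TAZ targets stood higher on replicate 1, with medians of 0.62 in PC9 and 0.33 in MTAC-P. CCN1 differed by 2.51 and 0.74, CCN2 by 4.14 and 1.49 and ANKRD1 by 3.67 and 1.71. Among NF-kB targets, CCL20 differed by -2.72 and -2.21, CXCL1 by -1.76 and -1.34 and CXCL2 by -1.78 and -1.77. Of 10000 random lists matched on level, 0 lay as far out in both lines as the YAP and TAZ list (adjusted p = 0.00165 over 33 lists, 6 of which passed, from the smallest p that 10000 lists can give). This argues against a chance draw of unrelated genes. The estimated correlation was 0.50 among YAP and TAZ targets and 0.33 among NF-kB targets, and random lists do not keep it. Genes that vary together can shift a list median between any 2 arrays, and the same sign in both lines can arise by chance. The test therefore cannot show that the lines share a replicate effect. The smaller YAP and TAZ median was still 0.26 after the trend with gene length, density and level was removed, which argues against that trend. RNA quality stays open, since ACTB's 3' minus 5' difference was lower on replicate 1 in both lines, by -0.24 in the line with the smaller difference. For GAPDH the duplicates were close, at -0.057 and 0.038 in PC9 and -0.090 and -0.069 in MTAC-P. The design gives no biological explanation to test. Culture density or handling shared by same-numbered samples may be a candidate explanation, which was not tested because the labels record neither.

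Genes that neighbour each other in the reference order tended to differ together. In 2884 overlapping windows of 25 neighbouring genes, which are not separate runs, 21 medians lay above and 21 below those of 100 shuffled gene orders, against 4 between the PC9 duplicates and 7 between the MTAC-P duplicates. From CRYBB1 to UQCR10, a run that holds XBP1, THOC5, ZMAT5 and NEFH, 23 of 25 genes were higher in MTAC-P, with a median of 0.65. From SKIC3 to SLC25A46, a run with RHOBTB3, ELL2, RGMB and GLRX, 2 of 25 were higher, with a median of -0.76. The line difference also followed gene density, from a median of -0.11 in the sparsest 20% of genes to 0.14 in the densest 20%. With that trend removed, 27 windows still lay beyond the shuffled orders, which argues against it as the whole account. The difference MTAC-P minus PC9, with the trend removed, was also taken from the replicate 1 arrays and from the replicate 2 arrays. The labels do not pair these numbers. Window medians of these 2 differences correlated across 587 windows at r = 0.69. Shuffled gene orders gave a median of 0.35 and a highest value of 0.45, which argues against array noise. A copy number difference between the lines may account for the runs, the most raised of which had a median of 0.72 with the trend removed, but no DNA was measured, and a regional difference in transcription cannot be told apart from it.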
